A study of Mus musculus with 30 samples.

How the data were processed

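RNA was measured in 30 libraries, from 6 cell populations sorted by flow cytometry out of each of 5 MMTV-PyMT tumours of FVB/N mice. Per the labels, tumours were digested with collagenase I and DNase, RNA was extracted with an RNeasy Plus Micro kit, and libraries were made with SMARTseq v4 and Ovation Ultralow V2 kits and pooled over 3 rapid lanes on an Illumina HiSeq. The authors list Trimmomatic 0.36, HISAT2 2.0.4, SAMtools 1.3.1, DESeq2 1.26 and the mouse build mm10. The counting tool, its strand setting and its annotation are not given in the sources used here. The deposited raw values are counts, whole numbers of reads per Entrez gene. The authors' normalised values, a signal on a linear scale, are the same counts divided by 1 size factor per library, as checked for every gene (largest relative spread 1.3e-09). The deposited matrix holds 14118 genes, each with at least 72 counts over all libraries, so genes with lower totals are absent. It holds no mitochondrial genes. A symbol was found for 14104 genes, and the 14 without one hold 0.0107% of counts. Coordinates are those of GRCm38.p6, the same assembly as mm10.

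Libraries were grouped by their labels. The columns of 2 libraries, CD206neg of tumours 6 and 8, are named for high MHC class II while their labels give low, and the labels were followed. The 6 populations of a tumour come from the same animal, so the tumour number pairs the libraries. The correlation of deviations from the group means between libraries of the same tumour was 0.0205 to 0.381 in the fibroblast fit, 0.111 to 0.648 in the macrophage fit and 0.0213 to 0.574 in the fit of all libraries. The main fits carry no block, and values with tumour as a block stand beside a result where they change its call or move a count over 1.5 times.

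Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, scaled by TMM, and tested by edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CAF1 and CAF2 had a fit of 10 libraries (12149 genes, biological coefficient of variation 0.337), the 3 macrophage comparisons a fit of 15 libraries (11052 genes, 0.364), and the comparisons between lineages a fit of 30 libraries (13610 genes, 0.387). The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts divided by the library total, on the usual scale. Their SD is over the 5 tumours of a group, or over all libraries of a side that joins groups. For the comparison of angiogenic genes over populations, CPM were scaled by TMM factors (0.5493 to 1.672). The mean of several groups is taken on the log2 scale.

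Gene lists, 38 in number and fixed before the data were examined, cover cell identity, function, dissociation quality and other cell types, and 28 of them have all members in the matrix (457 of 484 members). They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of the fit, and again with an estimated correlation and with fry. Genes named in the text follow a rule fixed with the lists: genes of the sort markers, the 8 largest rises and 8 largest falls at a mean of at least 10.0 CPM in the higher group with the same direction in 5 of 5 tumours, and up to 2 members per list and direction, with Lcn2 in the fibroblasts named beyond the rule. Genes with a group in which no library exceeds 3 counts are given in CPM without a fold change, and fold changes against groups just above that depend on the fit's prior count.

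Alternatives were tumour as a block, DESeq2 1.42.0, RLE factors, no filter, a filter of 50.0 counts in 5 libraries, a limit of 2-fold, a robust fit, voom with quality weights, limma on the authors' normalised values with a pseudocount of 1, another set of libraries in the fit, and each library left out in turn. Leaving out each tumour, and leaving out the 2 CD206neg libraries of tumours 6 and 8, were added after the data were seen. Each comparison was also run on 100 groupings of its libraries, the real one included. The tests were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold: edgeR found 31.0% to 84.0% of the former and 92.0% to 99.0% of the latter, with 4.65% to 7.48% false among its calls, and DESeq2 had 11.7% to 23.2% false. Camera found each list of changed genes. It gave 1 of the 6 lists of unchanged genes, in the simulation of CD206hi against CD206neg, a p of 0.00454 (0.0105 with an estimated correlation), and the others 0.693 or more. The simulated counts had no tumour effect and no correlation between genes, so these rates need not hold for the paired libraries.

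Totals per library of 6292411 to 11957076 counts put 3 counts, the upper 95% limit for a gene with none, at 0.251 to 0.477 CPM. These floors cover counting error only, and the SE and SD of a single group come from its 5 tumours. Where a side of a comparison joins several groups, its libraries come from the same 5 tumours. The SD then runs over all libraries of that side and also holds differences between its groups. The SE then treats libraries of the same tumour as independent. The 10 most abundant genes took 7.66% to 28.4% of a library's counts. Within groups no library is a copy of another: over the 60 pairs of libraries of the same group, the chi-squared of their difference per degree of freedom was 26.3 to 218.2. Results for some single genes are not reported here. Reads were not realigned, and GC content and gene length were not examined.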

Results

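The 30 libraries are bulk RNA-seq of 6 cell populations sorted from each of 5 MMTV-PyMT mammary adenocarcinomas, a mouse model in which the polyoma virus middle T antigen drives tumours of the mammary epithelium. The tumours came from 5 separate mice, had reached 750 mm3 and are numbered 5, 6, 8, 10 and 11 in the labels, so n = 5 libraries in every group. Cancer-associated fibroblasts (CAFs) were sorted as CD45-negative, CD31-negative and CD90-positive, and were parted by CD34 into CAF1 (CD34-negative) and CAF2 (CD34-positive). Endothelial cells were CD45-negative and CD31-positive. Tumour-associated macrophages (TAMs), positive for CD45 and F4/80, were parted by CD206 and MHC class II into the groups CD206hi MHCIIlo, CD206neg MHCIIlo and CD206pos MHCIIhi, called CD206hi, CD206neg and CD206pos from here on. Total counts per library ran from 6292411 to 11957076 (n = 30), and 11514 to 13756 genes were detected per library. A count of 3 corresponds to between 0.251 and 0.477 CPM (counts relative to the library total), depending on the library.

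Transcripts of the sort markers followed the gates, with exceptions among the macrophages. Pecam1, which encodes CD31, stood at 927 ± 294 CPM in endothelial libraries (SD, n = 5) and at most 1.81 ± 0.955 CPM in the mean of any other group. Adgre1, which encodes F4/80, stood at 645 ± 203, 492 ± 151 and 616 ± 302 CPM in the CD206hi, CD206neg and CD206pos groups, and below 1 CPM in every CAF and endothelial library. Cd34 was at 1603 ± 247 CPM in CAF2 and 53.8 ± 31.6 CPM in CAF1, and Mrc1, which encodes CD206, at 67.8 ± 32.7 CPM in CD206neg against 989.7 ± 301 in CD206hi and 1206 ± 538 in CD206pos. H2-Aa, an MHC class II chain, split the CD206neg group: the libraries of tumours 6 and 8 held 7874 and 2778 CPM, and the other 3 held 20.2 to 390.7 CPM. The data columns of those 2 libraries are named MHCII high, whereas the sample labels give MHCII low for all 5, and the labels were followed here. By Spearman correlation, the nearest library was of the same lineage for 30 of 30 libraries and of the same group for 24 of 30, with 2 of 5 each in CD206hi and CD206pos.

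Epithelial transcripts were present in sorted stromal libraries. Epcam, a surface protein of epithelial cells, averaged 254 ± 172 CPM in CAF1, 302 ± 192 in endothelial cells and 21.7 ± 41.6 in CAF2 (SD, n = 5 each), where tumour 6 held 96.1 CPM and the other 4 tumours 1.20 to 4.82 CPM. In the macrophage groups Epcam averaged 26.05 ± 32.03 CPM in CD206hi, 40.93 ± 37.4 in CD206neg and 28.6 ± 43.08 in CD206pos. Krt14, a keratin of myoepithelial cells, averaged 661 ± 1011 CPM in CAF1, with a range of 44.4 to 2448, and 1.74 ± 2.17 in CAF2. Rgs5, a marker of pericytes, ranged from 3.50 to 991.8 CPM over the endothelial libraries.

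**Figure D1:**
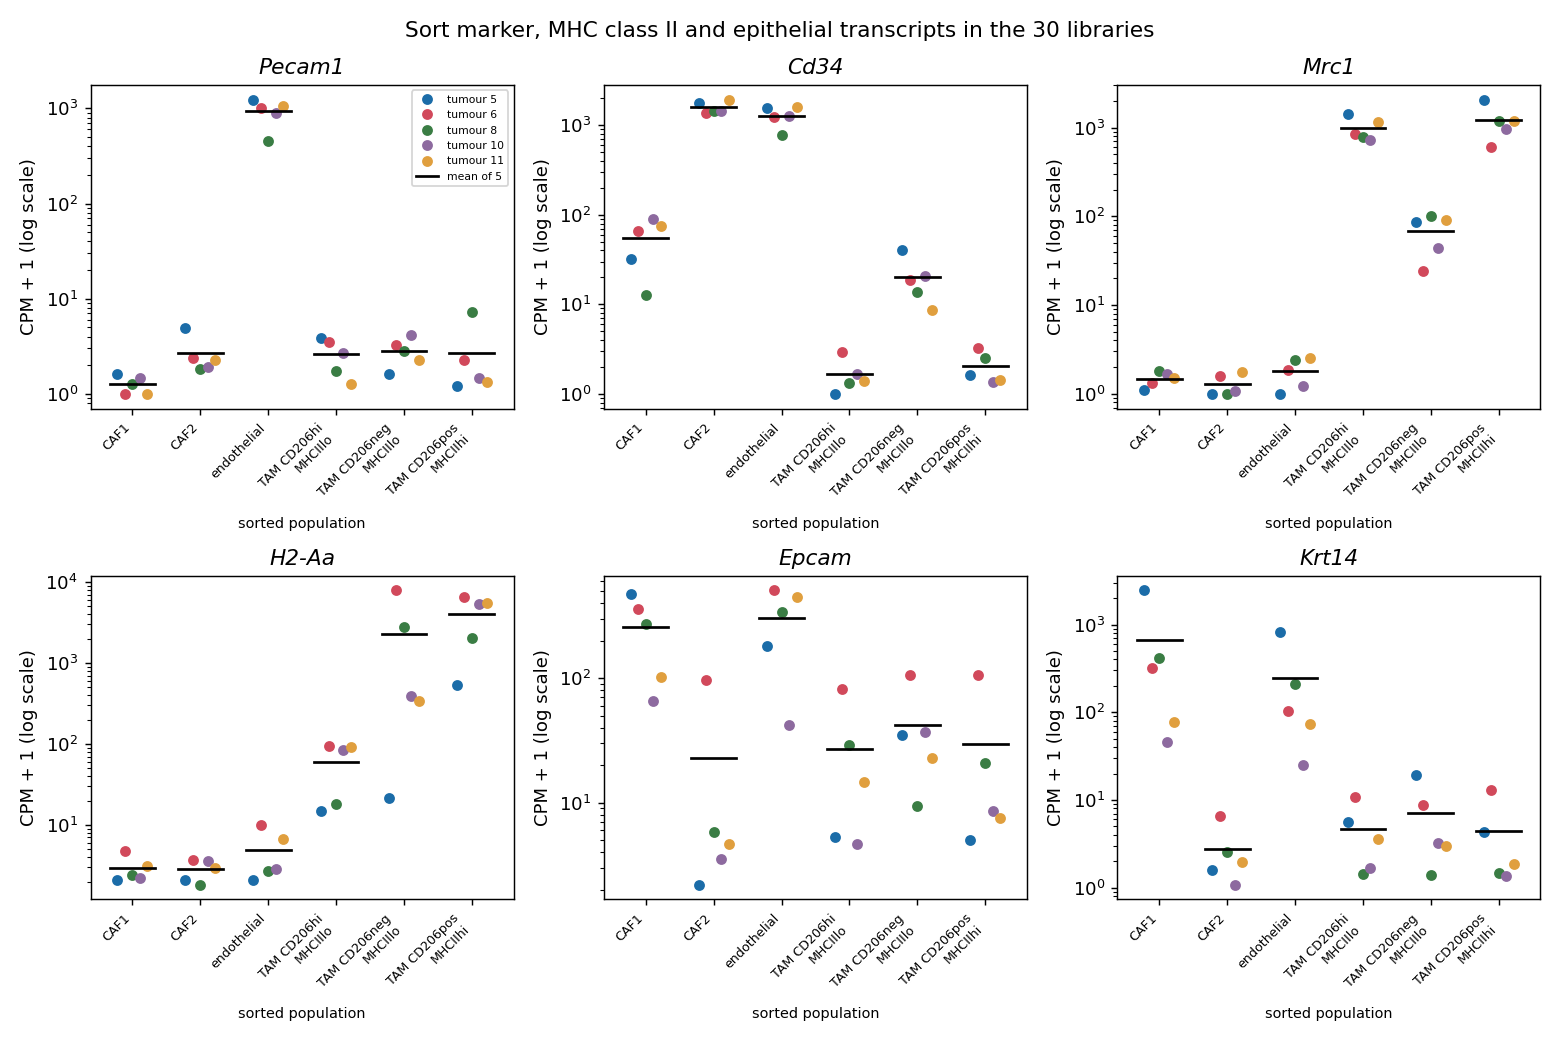
Each panel shows 1 transcript, with CPM plus 1 on a log axis for every library of the 6 sorted groups, n = 5 tumours per group. Cd34 separates CAF2 from CAF1, Mrc1 separates CD206neg from the other macrophage groups, and H2-Aa spreads from 20.2 to 7874 CPM within CD206neg. Epcam and Krt14 have their highest group means in CAF1 and endothelial libraries, and Epcam is also detected in the macrophage libraries.

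CAF1 and CAF2 share the CD90 gate and differ in CD34, and their comparison asks which transcripts part these sorted subsets. Bulk libraries do not show whether a difference arises within fibroblasts or from other cells in a gate. For pericytes in the CAF1 gate this was not tested. Genes of pericytes and vascular smooth muscle were higher in CAF1: all 16 tested members of that list rose. Notch3, a receptor of mural cells (Entrez gene 18131, chromosome 17, 32120820 to 32166896 in mm10), had a log2 fold change of 5.33 ± 0.44 (SE, n = 5 per group) and stood at 58.8 ± 38.6 CPM in CAF1 and 1.46 ± 0.744 CPM in CAF2 (SD). Higd1b and Cox4i2, mitochondrial proteins typical of pericytes, had log2 fold changes of 8.88 ± 0.86 and 6.49 ± 0.58, and Pdgfrb, the receptor for PDGF-B, was 5.71-fold higher (log2 2.51 ± 0.26). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these 4 genes had adjusted p values of 1.16e-05, 3.32e-05, 1.9e-05 and 4.56e-05. Limma's camera test of the pericyte list gave an adjusted p of 3.89e-27, and 0.0388 with an estimated correlation. All genes named as higher or lower between CAF1 and CAF2 differed in that direction in 5 of 5 tumours.

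Myofibroblast genes moved the same way, with 9 of 13 members higher in CAF1 and 11 when adjusted over the list alone. Tagln and Tpm2, proteins of the contractile apparatus, had log2 fold changes of 2.97 ± 0.30 and 2.61 ± 0.28 (edgeR adjusted p = 4.39e-05 and 5.35e-05). Camera gave this list an adjusted p of 8.95e-13, and 0.00122 with an estimated correlation. Acta2, Tagln, Myl9 and Cnn1 are members of both the pericyte and the myofibroblast list. Among fibrillar collagens 2 of 7 rose, Col11a1 by 3.63 ± 0.65 on the log2 scale, while the list itself had an adjusted p of 0.0698. Of the matrix proteases and crosslinkers, 6 of 18 rose and 1 fell (camera adjusted p = 0.346): the stromelysin Mmp11 rose by 2.10 ± 0.32 and the aggrecanase Adamts5 had a log2 fold change of -2.13 ± 0.37.

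Genes of adventitial fibroblasts were lower in CAF1, with 8 of 10 members passing and 9 when adjusted over the list alone. Sema3c, a secreted semaphorin (Entrez gene 20348, chromosome 5, 17574816 to 17730268), was 33.4-fold lower in CAF1, at 17.7 ± 7.7 against 636 ± 137 CPM (log2 -5.06 ± 0.31). Cd55, an inhibitor of complement, had a log2 fold change of -4.38 ± 0.24, and Cd34, the marker the gate used and itself a member of this list, -4.65 ± 0.57. The edgeR adjusted p values of these 3 genes were 1.83e-06, 1.17e-06 and 0.000146. Camera gave the list 1.43e-20, and an adjusted p of 0.0388 with an estimated correlation. Among the largest falls were Efhd1 (log2 -5.70 ± 0.40), the receptor tyrosine kinase Ret (-5.36 ± 0.37), the scavenging chemokine receptor Ackr2 (-5.60 ± 0.68) and the steroid dehydrogenase Akr1c18 (-5.54 ± 0.55). Of the inflammatory CAF list, 5 of 13 fell, and 1 rose and 6 fell when adjusted over the list alone. Its members Ly6c1, whose reads can be shared with the similar gene Ly6c2, and Dpt, a matrix protein, had log2 fold changes of -3.84 ± 0.62 and -3.06 ± 0.74, and the list had an adjusted p of 0.000779 that was 0.42 with an estimated correlation. General fibroblast genes went both ways, 2 up and 2 down of 13, with a median log2 fold change of 0.21, a mean of 0.03 and a camera direction of down (adjusted p = 0.671).

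Basement membrane, endothelial and angiogenic factor genes went both ways between CAF1 and CAF2. Basement membrane genes rose in 7 and fell in 3 of 15 cases, 7 and 4 when adjusted over the list alone, with Agrn (agrin, log2 2.02 ± 0.17) and the collagen IV chain Col4a2 (2.39 ± 0.32) higher in CAF1. Of the endothelial list 6 genes were tested, of which 5 rose, among them the adhesion molecule Esam (182-fold) and the VEGF receptor Flt1 (log2 6.47 ± 0.69), and the angiopoietin receptor Tek fell (-3.81 ± 0.46), while Pecam1 averaged 0.266 ± 0.269 CPM in CAF1. Camera gave these lists adjusted p values of 0.0213 and 0.00153, which were 0.376 and 0.0405 with an estimated correlation. Of 23 angiogenic factors 8 rose and 4 fell, 11 and 8 when adjusted over the list alone (camera adjusted p = 0.631). The angiopoietin Angpt2 (4.47 ± 0.47) and Tgfb3 (1.46 ± 0.24) were higher in CAF1, and Pdgfc (-1.79 ± 0.34) was higher in CAF2.

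Lists of other cell types were tested between CAF1 and CAF2 as well. In CAF1, 9 of 14 luminal epithelial genes rose, and all 14 when adjusted over the list alone, with Krt7 at 3.96 ± 0.93 and the cadherin Cdh1 at 4.36 ± 1.03 on the log2 scale. Of the myoepithelial list 4 of 5 rose, with Krt14 at 8.30 ± 1.22 and Krt5 at 8.06 ± 1.14. Keratins are a gene family in which counting can divide reads between members. The CAF1 library of tumour 5 held the highest Krt14 level, 2448 CPM, and the other CAF1 libraries 44.41 to 415.8 CPM. It held 733.9 CPM of Krt5, and the others 16.19 to 96.31 CPM. Camera gave the luminal and myoepithelial lists adjusted p values of 9.92e-06 and 0.00436, which were 0.42 and 0.405 with an estimated correlation. Of the macrophage list 3 of 9 rose, with Cd68 at 1.72 ± 0.41 on the log2 scale (camera adjusted p = 0.0355, and 0.42 with an estimated correlation), and the call was lost without the CAF2 library of tumour 10 (0.0529) or the CAF1 library of tumour 6 (0.0641). The adipocyte and Schwann cell lists had adjusted p values of 0.101 and 0.413. The neutrophil list, not tested in this fit, summed to 991.7 CPM in CAF1 (210 to 2445) and 66.16 CPM in CAF2 (15.19 to 223). Of these sums Lcn2, also expressed by epithelial cells, made up 953.1 and 60.21 CPM.

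Interferon response, hypoxia and chemokine genes went in different directions. Of the interferon response list 6 of 20 fell in CAF1, among them the nucleic acid sensor Zbp1 (log2 -1.25 ± 0.21), with a camera adjusted p of 0.0355 that was 0.432 with an estimated correlation, 0.0781 without the CAF2 library of tumour 11 and 0.0617 without the CAF1 library of tumour 8. Of the hypoxia and glycolysis list 7 of 17 rose and 1 fell, 12 and 1 when adjusted over the list alone. Its camera adjusted p was 0.0308, 0.432 with an estimated correlation and 0.061 with tumour as a block. It was 0.0666, 0.0558 and 0.053 without the CAF2 library of tumour 11, the CAF2 library of tumour 8 and the CAF1 library of tumour 8. Among chemokines 3 of 19 rose and 3 fell (camera adjusted p = 0.584), with Cx3cl1 (2.12 ± 0.25) higher and Cxcl3 (-3.28 ± 0.57) lower in CAF1. The cell cycle list had a median log2 fold change of 0.46 (camera adjusted p = 0.193). Thy1, the shared gate marker CD90, did not pass (log2 0.13 ± 0.33, edgeR adjusted p = 0.836).

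In total, edgeR's quasi-likelihood test called 2370 of 12149 genes between CAF1 and CAF2, of which 1327 were higher and 1043 lower in CAF1, and 1638 differed at least 2-fold. These counts do not part differences within fibroblasts from a different mix of cells in the gates. Camera called 11 of 25 lists with the preset correlation and 4 with an estimated one: the pericyte, adventitial, myofibroblast and endothelial lists. The 2370 genes were reached by none of 99 other groupings of the same 10 libraries, whereas 28 other groupings called as many lists, and only for those 4 lists did no other grouping give a p as small.

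**Figure D2:**
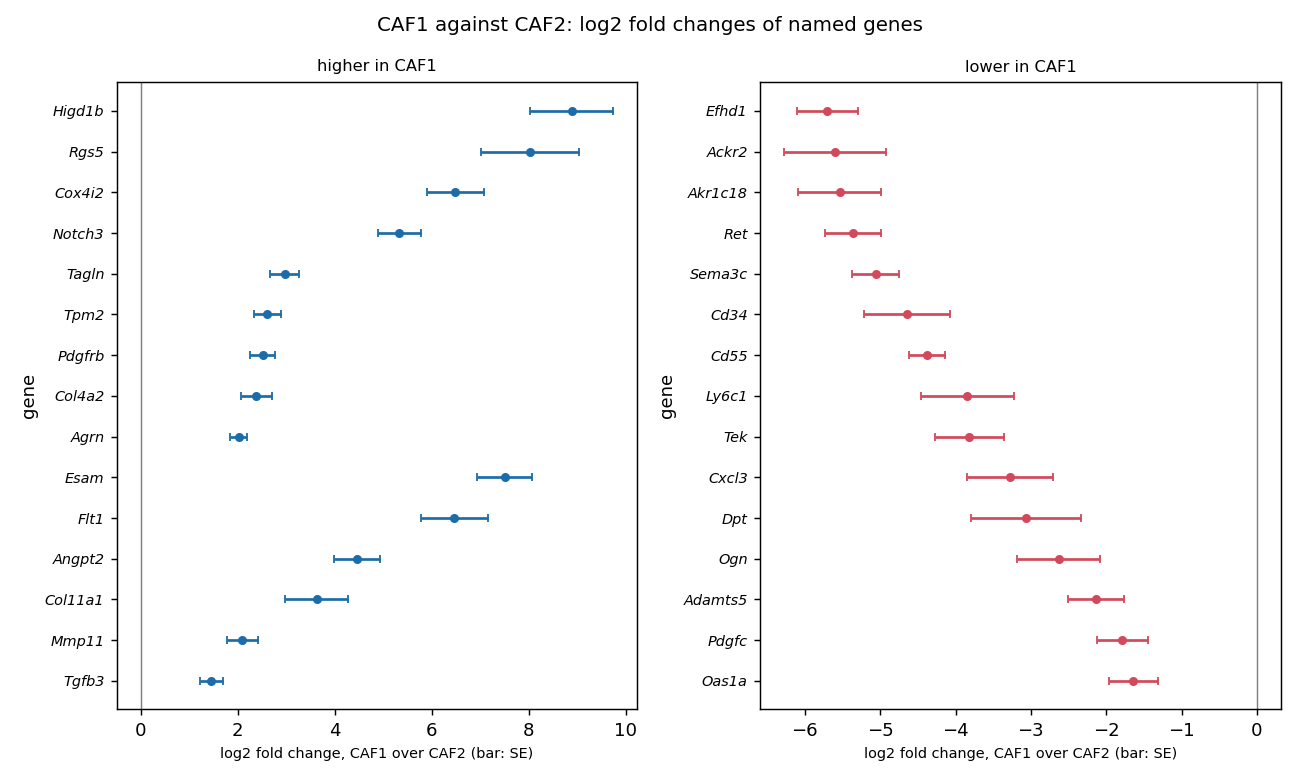
Log2 fold change of CAF1 over CAF2 with its SE for 30 genes, n = 5 libraries per group, from edgeR. Pericyte and contractile genes lie to the right of 0 (Higd1b at 8.88 ± 0.86) and adventitial genes to the left (Sema3c at -5.06 ± 0.31).

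CD206hi and CD206pos macrophages carry CD206 and differ in the MHC class II gate, and their comparison asks what else differs between them. Their labels also name the CD206 level differently, as high and as positive, while mean Mrc1 was not higher in CD206hi. F7 and F10, which encode the coagulation factors VII and X (Entrez gene 14068, chromosome 8, 13025506 to 13035809, and Entrez gene 14058, chromosome 8, 13037308 to 13056676), were 18.9-fold and 20.2-fold lower in CD206hi, at 1.29 ± 0.736 and 1.62 ± 1.09 CPM against 23.9 ± 19 and 30.3 ± 22.5 CPM (SD, n = 5). Their log2 fold changes were -4.24 ± 0.56 and -4.33 ± 0.61, lower in 5 of 5 tumours (edgeR quasi-likelihood adjusted p = 0.00524 and 0.00698). Both calls were lost when tumour 6 was left out of every group (0.0512 for each), and likewise for tumour 10 (0.107 and 0.148) or tumour 11 (0.0844 for each). MHC class II genes were lower in CD206hi as a list: 1 of 14 fell over all genes tested, 11 when adjusted over the list alone and 8 with tumour as a block, with a median log2 fold change of -2.73. Camera gave that list an adjusted p of 3.36e-22, and 0.0284 with an estimated correlation. H2-Aa and H2-Ab1 had log2 fold changes of -6.08 ± 1.34 and -5.64 ± 1.20, lower in 5 of 5 tumours, with edgeR adjusted p values of 0.0821 and 0.0675, and of 0.00316 and 0.00412 with tumour as a block. Without the CD206pos library of tumour 5, H2-Aa passed (0.0451), and H2-Ab1 passed without that library (0.0356) or the CD206pos library of tumour 8 (0.0468); reads of the H2 family can be shared between members. Mrc1, the gate's other marker, did not pass (log2 -0.20 ± 0.36, adjusted p = 0.943).

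Further lists fell in CD206hi. The monocyte list, with 1 of 7 members passing and 3 when adjusted over the list alone, had a median log2 fold change of -0.94, and the list of alternative activation, with 1 of 9 and 4, had -0.67. The passing member is the same gene in both lists. Their camera adjusted p values were 8.37e-06 and 9.27e-06, and 0.00641 for each with an estimated correlation. The dendritic cell and inflammatory cytokine lists had median log2 fold changes of -0.76 and -0.58 (camera adjusted p = 0.00069 and 0.00697, and 0.113 and 0.2 with an estimated correlation). Cell cycle, hypoxia and perivascular macrophage genes had median log2 fold changes of 0.54, 0.50 and 0.48, with camera adjusted p values of 5.31e-06, 0.0129 and 0.0321 and of 0.574, 0.629 and 0.714 with an estimated correlation. The hypoxia call was lost without the libraries CD206pos of tumour 11 (0.162), CD206hi of tumour 8 (0.103) or CD206hi of tumour 6 (0.0763). The perivascular call was lost without CD206hi of tumour 11 (0.665), CD206pos of tumour 8 (0.394), CD206pos of tumour 6 (0.106), CD206hi of tumour 6 (0.0913) or CD206pos of tumour 10 (0.0827).

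Over all genes, edgeR's quasi-likelihood test called 21 of 11052 between CD206hi and CD206pos, 1 higher and 20 lower in CD206hi, all 21 at least 2-fold, and 97 (6 higher, 91 lower) with tumour as a block. The count moved with single libraries: it was 8, 12, 13, 8 and 8 without the CD206hi library of tumours 5, 6, 8, 10 and 11, and 39, 9, 48, 5 and 8 without the CD206pos library of the same tumours. Leaving tumour 6, 10 or 11 out of every group gave 0 genes in edgeR, with 723, 437 and 609 genes at an unadjusted p under 0.05, and 50, 34 and 53 genes in DESeq2, 37, 41 and 42 with the block and 0 in voom. Leaving out tumour 5 or 8 gave 30 or 19 genes in edgeR. Of 100 groupings of these libraries, the real one included, 7 called as many genes, and the other 6 (42, 55, 71, 82, 325 and 789 genes) each put both libraries of at least 1 tumour on the same side. The 13 other groupings that keep every tumour in both groups called 0 genes at most in edgeR's test. As many lists were called by 19 of the 100, while only for the MHC class II, monocyte and alternative activation lists did no other grouping give a p as small.

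CD206hi and CD206neg macrophages differ, per the labels, in the CD206 gate at low MHC class II. The 16 tested genes of perivascular and tissue-resident macrophages were higher in CD206hi in 14 cases, 15 when adjusted over the list alone and 16 with tumour as a block. Lyve1, a hyaluronan receptor (Entrez gene 114332, chromosome 7, 110850607 to 110862953), stood at 269 ± 192 CPM in CD206hi and 0.491 ± 0.382 CPM in CD206neg (SD, n = 5), a log2 fold change of 8.90 ± 0.91. Cbr2, a carbonyl reductase (Entrez gene 12409, chromosome 11, 120729485 to 120732025), was 67.7-fold higher (log2 6.08 ± 0.56), Cd163, the haemoglobin scavenger receptor, had a log2 fold change of 7.09 ± 0.79, and Mrc1, the marker of the gate, 3.78 ± 0.40. The edgeR adjusted p values of these 4 genes were 1.97e-05, 7.21e-06, 2.65e-05 and 2.17e-05. Camera gave the perivascular list, in which Mrc1 is counted, an adjusted p of 3.08e-44, and 0.00338 with an estimated correlation. The growth factor Igf1 (3.60 ± 0.45), the chemokine Pf4 (3.86 ± 0.41), the eotaxin Ccl24 (7.31 ± 0.60) and the lectins Cd209f (9.60 ± 1.36) and Cd209g (8.52 ± 1.25) were also higher, the last 2 within a family whose members are similar enough to share reads. All genes named as higher or lower in the comparisons with CD206neg differed in that direction in 5 of 5 tumours.

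CD206neg macrophages held more transcript of other kinds. Dcstamp, a membrane protein of cell fusion (Entrez gene 75766, chromosome 15, 39745930 to 39760938), was 27.7-fold lower in CD206hi (log2 -4.79 ± 0.53), and Cd34 (-5.01 ± 0.66), the langerin gene Cd207 (-4.47 ± 0.76) and the integrin Itgax (-2.89 ± 0.46) were lower too. Of the inflammatory cytokines 3 of 9 fell, 5 when adjusted over the list alone, with Il12b at -3.96 ± 0.70 and Il1a at -1.72 ± 0.36, and the camera adjusted p was 0.00362, or 0.288 with an estimated correlation. Vegfa, an angiogenic factor induced by low oxygen, was lower in CD206hi (-1.71 ± 0.34) and Pdgfc higher (2.54 ± 0.42). Of the hypoxia list 3 of 18 fell (camera adjusted p = 0.0062, 0.639 with an estimated correlation and 0.0558 without the CD206hi library of tumour 11). Among 22 chemokines 8 rose and 4 fell, 9 and 5 when adjusted over the list alone, with Cxcl16 (-1.57 ± 0.30) and Ccl22 (-3.37 ± 0.69) lower in CD206hi (camera adjusted p = 0.00403, and 0.639 with an estimated correlation). Of 10 complement genes 4 rose, among them C1ra (2.38 ± 0.39), with a camera adjusted p of 0.0106, and 0.639 with an estimated correlation. Immediate early genes rose in 2 of 17 cases (camera adjusted p = 0.0162, and 0.794 with an estimated correlation), a call lost without CD206hi of tumour 11 (0.306), CD206neg of tumour 5 (0.0691) or CD206neg of tumour 8 (0.0634).

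MHC class II genes were lower in CD206hi than in CD206neg in 11 of 14 cases (camera adjusted p = 7.47e-07, and 0.639 with an estimated correlation), in a comparison that includes the CD206neg libraries with H2-Aa at 7874 and 2778 CPM. H2-Aa, H2-Ab1 and Cd74, the invariant chain, had log2 fold changes of -5.64 ± 1.31, -5.50 ± 1.19 and -4.26 ± 0.95 (edgeR adjusted p = 0.0089, 0.00534 and 0.00644). All 3 calls ended when the CD206neg libraries of tumours 6 and 8 were left out, with adjusted p values of 0.212, 0.117 and 0.0814. Without tumour 6 in any group, H2-Aa had 0.0778 and Cd74 0.075.

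In total, edgeR's quasi-likelihood test called 1110 of 11052 genes between CD206hi and CD206neg, 679 higher and 431 lower in CD206hi, 840 of them at least 2-fold, and 1791 with tumour as a block. The count fell to 545 without the CD206neg libraries of tumours 6 and 8, to 652 without tumour 6 and to 535 without tumour 11. None of 99 other groupings reached 1110, with 60 at most, while 49 called as many lists as the 7 of 23 found here, and only for the perivascular list did none give a p as small.

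Per the labels, CD206pos and CD206neg macrophages differ in the CD206 and MHC class II gates. However, H2-Aa in the CD206neg libraries of tumours 6 and 8 (7874 and 2778 CPM) exceeded that in CD206pos of the same tumours (6590 and 2058 CPM). Perivascular genes, with the gate marker Mrc1 counted among them, were again higher in the CD206-bearing group, 14 of 16 and 15 when adjusted over the list alone. Lyve1 had a log2 fold change of 8.06 ± 0.89, Cd163 of 7.33 ± 0.80, Cbr2 of 5.35 ± 0.54 and Mrc1 of 3.98 ± 0.40 (SE, n = 5 per group, edgeR adjusted p = 3.19e-05, 2.73e-05, 1.58e-05 and 1.58e-05). The CD206pos library of tumour 5 held 528.4 CPM of Lyve1 and the other 4 held 57.85 to 83.54 CPM. Without it the log2 fold change of Lyve1 was 6.969. Camera gave an adjusted p of 1.54e-30, and 0.014 with an estimated correlation. Retnla, a secreted product of alternatively activated macrophages (Entrez gene 57262, chromosome 16, 48842609 to 48844461), stood at 5245 ± 3640 CPM in CD206pos and 14.7 ± 14.2 CPM in CD206neg (log2 8.32 ± 1.36), and Il10, an anti-inflammatory cytokine, was 4.23-fold higher (2.08 ± 0.40). Both belong to the alternative activation list, of which 4 of 9 rose, and 6 rose and 1 fell when adjusted over the list alone. The monocyte list rose in 4 of 7 cases, with the chemokine receptor Ccr2 at 3.07 ± 0.42. The last 2 lists had camera adjusted p values of 0.00515 each, and 0.0555 each with an estimated correlation. Timp1 (4.80 ± 0.76), an inhibitor of matrix proteases, the protease Mmp19 (2.71 ± 0.53) and Ccl24 (7.80 ± 0.61) were higher in CD206pos as well.

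Of the hypoxia and glycolysis list 9 of 18 fell and 1 rose in CD206pos against CD206neg, 11 and 1 when adjusted over the list alone, with the enzymes Aldoa at -1.96 ± 0.32 and Ldha at -1.58 ± 0.30 (camera adjusted p = 9.06e-05, and 0.417 with an estimated correlation). Lipid-associated macrophage genes fell in 4 of 16 cases, with 2 up and 8 down when adjusted over the list alone, and the galectin Lgals3 had a log2 fold change of -1.98 ± 0.43. That list had a camera adjusted p of 0.0241, 0.417 with an estimated correlation, 0.0604 without the CD206neg library of tumour 11 and 0.0858 without the CD206pos library of tumour 8. The cell cycle list had a median log2 fold change of -0.94, with 1 of 20 lower, 5 when adjusted over the list alone and 17 with tumour as a block (camera adjusted p = 1.52e-05, and 0.632 with an estimated correlation). Among 22 chemokines 9 rose and 3 fell, 9 and 5 when adjusted over the list alone, with Cxcl14 at -3.24 ± 0.44 and Cxcl16 at -1.57 ± 0.30 (camera adjusted p = 0.000493, and 0.417 with an estimated correlation). The ectonucleotidase Nt5e (-3.17 ± 0.76), the membrane protease Mmp14 (-1.93 ± 0.39), Il12b (-3.32 ± 0.68), Il1a (-1.74 ± 0.36) and Itgax (-2.05 ± 0.44) were lower in CD206pos. The MHC class II list had an adjusted p of 0.691 and H2-Aa a log2 fold change of 0.45 ± 1.08 (adjusted p = 0.828), and the list passed (0.000404) without the CD206neg libraries of tumours 6 and 8.

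In total, edgeR's quasi-likelihood test called 1625 of 11052 genes between CD206pos and CD206neg, 978 higher and 647 lower in CD206pos, 1079 of them at least 2-fold, and 2800 with tumour as a block. The count was 1074, 1064, 765 and 818 without tumours 5, 6, 10 and 11 in turn, and 930 without the CD206neg libraries of tumours 6 and 8. None of 99 other groupings reached 1625, with 280 at most, while 31 called as many lists as the 7 of 23 found here, and only for the perivascular and monocyte lists did none give a p as small.

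**Figure D3:**
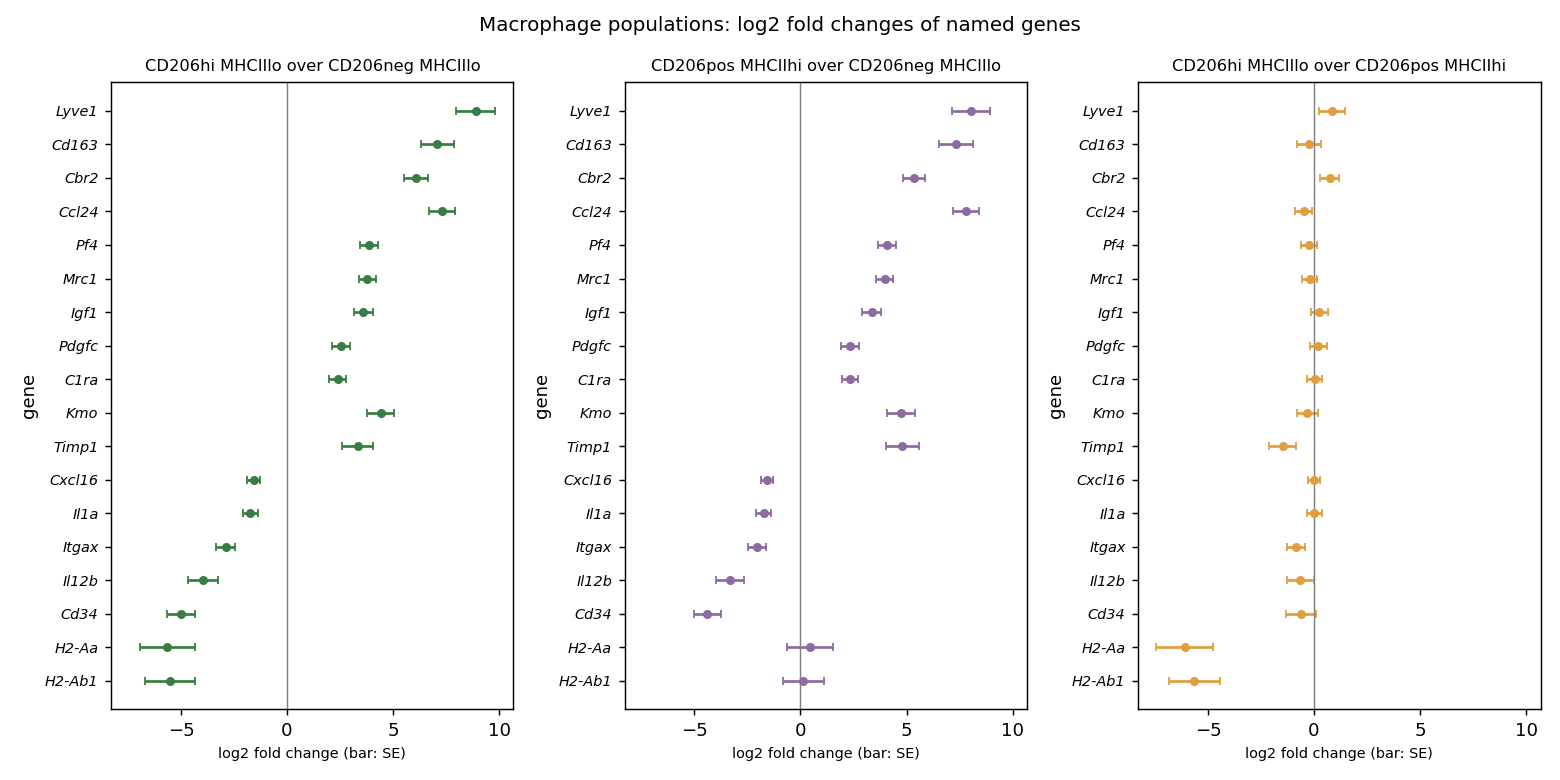
Log2 fold change with its SE for 18 genes in the 3 comparisons of macrophage groups, n = 5 libraries per group, from edgeR. Perivascular genes such as Lyve1 (8.90 ± 0.91 and 8.06 ± 0.89, the latter 6.969 without the CD206pos library of tumour 5) lie to the right of 0 in both comparisons with CD206neg. MHC class II genes lie to the left in both comparisons of CD206hi, which share the CD206hi libraries, at -6.08 ± 1.34 and -5.64 ± 1.31 for H2-Aa. Against CD206pos, H2-Aa did not pass without a block. Its call against CD206neg ended without the CD206neg libraries of tumours 6 and 8.

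Endothelial libraries were compared with the mean of CAF1 and CAF2 to find the transcripts of each lineage. All 15 endothelial genes were higher in endothelial cells. Pecam1 (Entrez gene 18613, chromosome 11, 106654213 to 106715281) had a log2 fold change of 10.04 ± 0.55 and Egfl7, a secreted endothelial factor, of 9.46 ± 0.43 (SE, n = 5 against 10 libraries, from the same 5 tumours). The orphan receptor Tie1 (Entrez gene 21846, chromosome 4, 118471191 to 118489849) stood at 519.9 ± 178 CPM against 0.108 ± 0.131 CPM in CAFs (SD over the libraries of each side). Tip cell genes, active in vessel sprouts, rose in 8 of 8 cases, with the Notch ligand Dll4 at 394 ± 155 against 0.217 ± 0.435 CPM and the peptide Apln at 5.63 ± 0.44 on the log2 scale. Receptors of angiogenic factors rose in 10 and fell in 6 of 18 cases, with Flt4 (112 ± 37.7 against 0.154 ± 0.211 CPM) and the semaphorin receptor Plxnd1 (log2 4.71 ± 0.26) higher and Pdgfra (-7.61 ± 0.58) and Tgfbr2 (-2.67 ± 0.33) lower in endothelial cells. General fibroblast genes fell in 13 of 13 cases, with the proteoglycan Dcn (Entrez gene 13179, chromosome 10, 97479500 to 97518163) at -9.19 ± 0.90 and Fstl1 at -4.28 ± 0.37. Camera gave the endothelial, tip cell, receptor and fibroblast lists adjusted p values of 1.09e-26, 1.54e-08, 0.000185 and 1.97e-12, and of 0.000189, 0.00405, 0.034 and 0.034 with an estimated correlation. The lists overlap: Kdr, Flt1, Tek and Tie1 are members of both the endothelial and the receptor list, and Pdgfra of both the receptor and the fibroblast list. In edgeR's quasi-likelihood test, Pecam1, Tie1, Egfl7 and Dcn had adjusted p values of 5.8e-15, 6.05e-18, 1.31e-16 and 1.38e-09, and the genes named for this comparison differed in the stated direction in 5 of 5 tumours.

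Other groups went both ways between endothelial cells and CAFs. Among basement membrane genes 7 of 15 rose and 3 fell (camera adjusted p = 0.119), with the laminin chain Lama5 (5.08 ± 0.58) and nidogen Nid2 (3.43 ± 0.32) higher and Lama2 (-4.47 ± 0.51) lower in endothelial cells. Of 24 angiogenic factors 7 rose and 13 fell (camera adjusted p = 0.119), with Pdgfb (58.2 ± 25.3 against 1.54 ± 2.99 CPM) higher and Fgf7 (log2 -8.30 ± 0.76) and Sema3c (-5.69 ± 0.48) lower. Pericyte genes rose in 6 and fell in 2 of 17 cases, 5 and 6 with tumour as a block, with a median of 0.58, a mean of 0.67 and a camera direction of down (adjusted p = 0.93), while Rgs5 in the endothelial libraries ran from 3.50 to 991.8 CPM. Immediate early genes, a sign of dissociation stress, fell in 10 of 17 cases, 13 when adjusted over the list alone, among them Egr1 (-2.09 ± 0.39) and Egr2 (-3.21 ± 0.40); camera gave 0.0103, an adjusted p of 0.705 with an estimated correlation and 0.0555 without tumour 8. Cell cycle genes rose in 11 of 20 cases, 18 with tumour as a block, with Cdk1 at 1.33 ± 0.33 and Aurkb at 1.28 ± 0.32 (camera adjusted p = 0.0166, 0.761 with an estimated correlation and 0.0627 without the endothelial library of tumour 8). Luminal epithelial genes rose in 6 of 15 cases, 9 when adjusted over the list alone and 14 with tumour as a block, and their camera adjusted p was 0.119, or 0.0217 with the block. In total, edgeR called 6145 of 13610 genes, 3135 higher and 3010 lower in endothelial cells, 3949 of them at least 2-fold.

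The mean of the 3 macrophage groups was compared with the mean of CAF1, CAF2 and endothelial cells, each group weighing the same on the log2 scale. All 15 general macrophage genes were higher in macrophages. Adgre1 (Entrez gene 13733, chromosome 17, 57358581 to 57483529) had a log2 fold change of 11.38 ± 0.35 (SE, n = 15 against 15 libraries, from the same 5 tumours). The Fc receptor Fcgr1 stood at 149 ± 33 against 0.207 ± 0.227 CPM (SD over the 15 libraries of each side). The chemokine receptor Ccr1 (628 ± 169 against 0.359 ± 0.407 CPM), the cytokine Osm (log2 12.06 ± 0.46), Cd83 (11.47 ± 0.47) and the leukocyte phosphatase Ptprc, which encodes CD45 (10.47 ± 0.37), were higher as well. All 15 basement membrane genes were lower, with nidogen Nid1 (Entrez gene 18073, chromosome 13, 13437602 to 13512275) at -10.60 ± 0.32 and the laminin chain Lamc1 at -4.60 ± 0.15. All 13 general fibroblast genes were lower, with Fstl1 at -9.74 ± 0.29 and Col5a1 at -9.22 ± 0.43, as were all 17 pericyte genes, among them Abcc9 (-4.99 ± 0.24), and 11 of 15 endothelial genes, among them Plvap (-7.71 ± 0.43). Camera gave the macrophage, basement membrane, fibroblast, pericyte and endothelial lists adjusted p values of 8.45e-25, 2.1e-22, 2.1e-09, 0.00022 and 0.00887, and of 0.00138, 0.000191, 0.193, 0.384 and 0.284 with an estimated correlation. The edgeR adjusted p values of Adgre1, Fcgr1, Nid1 and Fstl1 were 7.39e-22, 9.77e-25, 5.71e-22 and 4.52e-22, and the genes named for this comparison differed in the stated direction in 5 of 5 tumours.

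Angiogenic factors as a list were lower in macrophages, 16 of 24 falling and 7 rising, with a camera adjusted p of 0.0334, 0.329 with an estimated correlation, 0.0553 with tumour as a block, 0.0531 without the CD206neg libraries of tumours 6 and 8 and 0.0618 without tumour 5. Their receptors fell in 12 of 18 cases and rose in 4 (camera adjusted p = 0.126), and Tgfbr1 (2.43 ± 0.18) and Nrp2 (1.66 ± 0.19) were among those higher in macrophages. Of the interferon response list 10 of 21 rose and 4 fell (camera adjusted p = 0.266), with the antiviral genes Oas1a (2.66 ± 0.18) and Rsad2 (2.86 ± 0.23) higher in macrophages. Immediate early genes went both ways, 7 up and 4 down of 17 (camera adjusted p = 0.942), with Egr1 (-1.89 ± 0.24) and Jun (-1.77 ± 0.29) lower and Atf3 (1.02 ± 0.23) and Junb (1.03 ± 0.27) higher in macrophages. In total, edgeR's quasi-likelihood test called 9429 of 13610 genes, 4142 higher and 5287 lower in macrophages, 5760 of them at least 2-fold, with a median log2 fold change of -0.134 over all genes tested.

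Angiogenic factors and their receptors were then compared over the 6 populations, to find which sorted population held each most, in CPM scaled by TMM factors. All 42 genes differed between populations in edgeR's F test over 6 groups, and for 23 of them the highest group exceeded the next highest (Benjamini-Hochberg adjusted over the list alone). These were 11 in endothelial cells, 7 in CAF2, 3 in CAF1 and 2 in CD206neg macrophages, and 24 with tumour as a block. Vegfa was highest in CD206neg macrophages, at 174 ± 63.8 CPM against 73.3 ± 12.7 in CD206pos (SD, n = 5; log2 difference 1.25 ± 0.38, SE, adjusted p = 0.00777), as was Tgfbr1, with CD206hi next (1.01 ± 0.30, 0.00719). Endothelial cells led for Apln, at 234 ± 127 CPM against 6.96 ± 3.36 in CAF1 (5.05 ± 0.57, 8.39e-09), for Angpt2, at 249 ± 163 against 53 ± 19.5 (2.23 ± 0.51, 0.000685), and for the VEGF receptors Flt1 (3.83 ± 0.63, 7.3e-06) and Kdr (6.63 ± 0.68, 1.18e-09). CAF2 led for Sema3c, at 573 ± 91 against 17 ± 6.51 CPM in CAF1 (5.08 ± 0.47, 1.5e-10), for Vegfd, at 128 ± 28.7 against 36.2 ± 40.4 (1.83 ± 0.61, 0.0151), and for Pdgfd (1.39 ± 0.34, 0.00153). CAF1 led for Tgfb3, at 227 ± 68.2 against 83.6 ± 19.9 CPM in CAF2 (1.44 ± 0.45, 0.00866), and for Pdgfrb (2.50 ± 0.76, 0.00771). For Pdgfc, at 87.5 ± 45.1 CPM in CD206hi and 75.6 ± 50.4 in CD206pos, the leading groups were not separated (0.21 ± 0.52, 0.741).

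**Figure D4:**
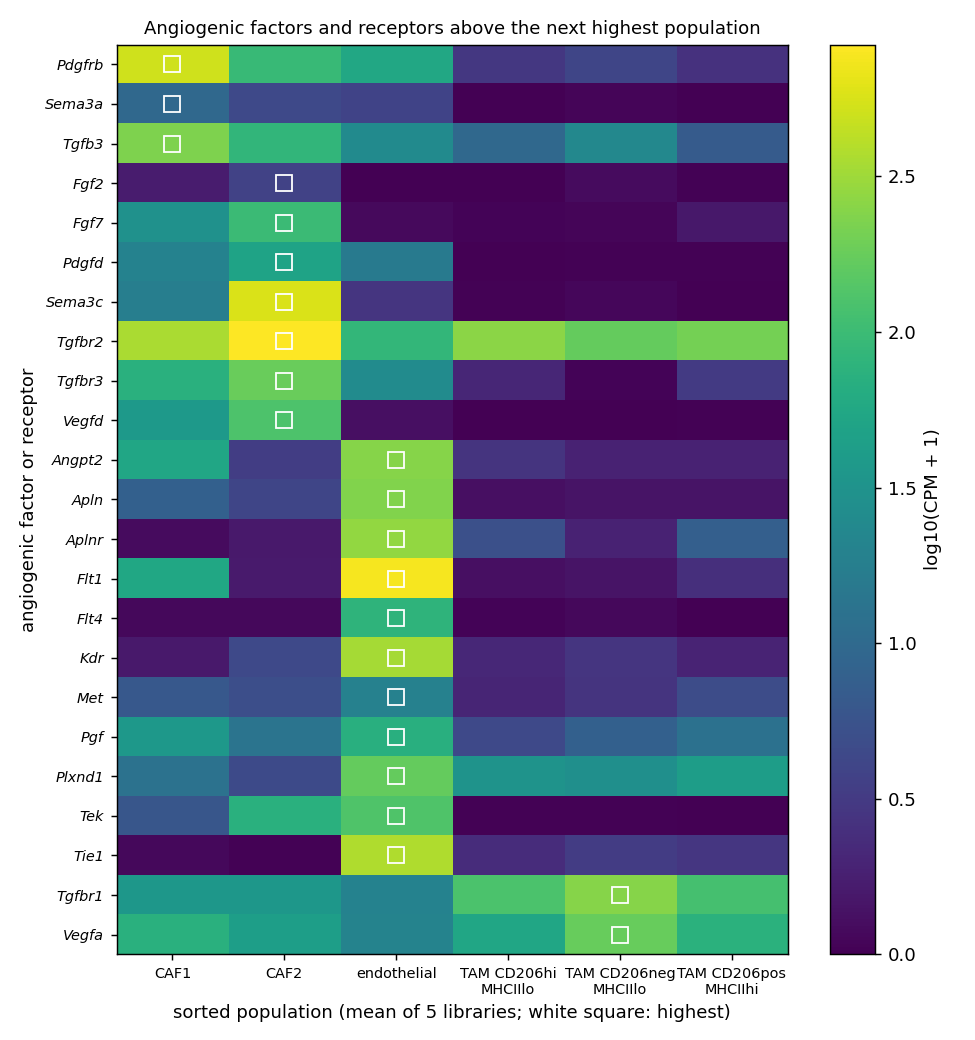
Mean TMM-scaled CPM plus 1, as log10, of the 23 angiogenic factors and receptors whose highest population exceeded the next highest, over the 6 sorted populations, n = 5 libraries each; a white square marks the highest. Endothelial cells hold 11 of the squares, CAF2 7, CAF1 3 and CD206neg macrophages 2.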

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

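All tests of explanations in this part were chosen after the result was seen. Marker transcripts were screened for a library far from the other 4 of its group (a gap of over 0.71 of the group's range). Of 85 groups 21 held one, and 15 of the 21 concern epithelial transcripts, 10 in tumour 6 and 5 in tumour 5. The cutoff gives about 1 in 20 for independent values of a normal shape. That rate is not the expectation here. CPM were screened without a log scale, transcripts of a library can move together, and all 21 distant libraries were the highest of their group.

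In tumour 6, a distant library was found in CAF2 for Epcam (96.1 CPM, others 1.20 to 4.82), Krt18 (163.8, others 0.400 to 11.1) and Krt8 (134.7, others 0 to 7.28). In the CD206hi library of tumour 6, Krt18 stood at 117.1 CPM (others 13.3 to 30.3) and Krt8 at 99.7 (others 10.7 to 29.4). In its CD206neg library, Epcam stood at 104.9 CPM (others 8.39 to 35.7) and Krt18 at 193.9 (others 5.12 to 45.7), and in its CD206pos library Epcam at 104.9 (others 4.05 to 19.9), Krt18 at 119.4 (others 8.56 to 26.1) and Krt8 at 80.6 (others 7.58 to 15.5). In tumour 5, the CAF1 library stood apart for Krt14 (2448 CPM, others 44.4 to 415.8), Krt17 (845.2, others 21.7 to 99.0) and Krt5 (733.9, others 16.2 to 96.3), and the endothelial library for Krt14 (817.3, others 24.0 to 211.5) and Krt17 (309.4, others 28.6 to 52.3).

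Other distant libraries were CAF1 of tumour 6 for Cd74 (43.9 CPM, others 8.66 to 16.9) and Lyz2 (47.1, others 11.3 to 13.8), and endothelial of tumour 6 for Lyz2 (62.2, others 11.1 to 22.2). CD206neg of tumour 11 stood apart for Lyz2 (31120 CPM, others 18450 to 19940), CD206pos of tumour 5 for Lyve1 (528.4, others 57.9 to 83.5), and endothelial of tumour 8 for Acta2 (1176, others 12.7 to 332.9).

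Luminal and myoepithelial transcripts were higher in CAF1 than in CAF2. A single epithelial mixture per tumour that entered both the CAF1 and the endothelial gate would give both the same myoepithelial to luminal ratio. The log2 ratio was 1.23 higher in CAF1 (SD 0.997, higher in 5 of 5 tumours), which argues against such a mixture as the only source. The mixture is not excluded, since the exact sign-flip p of 0.0625 is the smallest possible with 5 tumours. Transcription of these genes by CAF1 cells would also shift the ratio. That 94.7% of tested members (18 of 19) were higher in CAF1 restates the pattern, and this first test was replaced by the next one. Epithelial cells carried over with another makeup in the CAF1 gate could account for it, since 64.3% of tested luminal members (9 of 14) and 4 of 5 myoepithelial members were highest in the same CAF1 library, that of tumour 5, where 3 of the latter had already been seen to stand apart. Transcription of these genes by the CAF1 cells themselves (median log2 fold 3.38) cannot be told apart from that, because bulk libraries do not show which cell held a transcript and genes regulated together would also peak in 1 library.

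MHC class II transcripts differed between the CD206neg libraries. Another MHC class II gate in the 2 libraries whose columns are named MHCII high could account for it: the lower of them held 2778 CPM of H2-Aa, and the highest of the other 3 held 390.7. These values are the ones that showed the pattern, so they restate it and do not test the gate. Dendritic cells in these libraries cannot be told apart from such a gate, as 30% of dendritic cell genes (3 of 10: Xcr1, Batf3 and Kmo) were higher in both than in each of the other 3, with 10% expected by chance. Against dendritic cells, the labels give an F4/80 gate for these libraries and the summed list was flat, at 462.6 and 438.5 CPM in these libraries and 496, 408.3 and 379.6 CPM in those of tumours 5, 10 and 11, but members with a high level in macrophages would hide a small share of such cells. A higher level throughout tumours 6 and 8 also stays open: in the MHCII-high gate H2-Aa stood at 6590 CPM in tumour 6 and 2058 CPM in tumour 8, against 532.8, 5296 and 5461 CPM in tumours 5, 10 and 11, and the gate itself selects cells on MHC class II.

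Pericyte transcripts were present in the endothelial libraries. Cells of the CAF1 gate as sorted would bring pericyte genes and Col1a1 in their CAF1 ratio. Against Col1a1, the pericyte genes were higher by a log2 ratio of 5.53 (SD 2.37, above 0 in 5 of 5 tumours). This argues against such cells as the only source. It does not exclude them as a part, since transcripts of the list held by endothelial cells themselves would also raise the ratio. Pericytes alone carried into the endothelial gate could account for the pattern, since 88.2% of the list (15 of 17) was highest in the same library, that of tumour 8. That library also held the lowest Pecam1 and Cdh5 of the endothelial group, at 448.2 and 194.5 CPM against group means of 926.9 and 448.3 CPM. Whether it held a smaller share of endothelial cells was not tested. No biological explanation was tested for this pattern.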

How the results depend on the processing

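The values from leaving out a whole tumour, or the CD206neg libraries of tumours 6 and 8, were chosen after the data were seen; the other alternatives were fixed before. No named gene and no list called in the main fit reversed under any alternative. For genes and lists not called there, the direction was not compared. Among all genes called, the sign changed for 7 genes under voom, 2 under limma on the authors' values, 4 without the endothelial library of tumour 8 and 1 without tumour 8 for endothelial cells against CAFs, and for 1 gene each without the CAF2 library of tumour 6, the CD206pos library of tumour 8 or tumour 8 for macrophages against the rest. With each library left out in turn, 3053 of 3075 values of named genes kept their side of the threshold, 4 gained a call and 18 lost it, and for lists 1775 of 1840 stayed, 43 gained and 22 lost a call. Under DESeq2 200 of 203 named genes stayed and 3 gained a call. Under voom with quality weights 199 stayed, and under limma on the authors' values, no filter and the robust fit 202 each. With a tumour left out, 193 (tumour 6) to 199 (tumours 5 and 8) stayed. RLE factors moved none of 203 genes and 134 lists. The leading group was separated for 23 angiogenic genes in the main fit and 24 with tumour as a block, and 24 of 30 libraries were nearest to their own group in every setting.

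With each library left out in turn, the gene counts ran from 1721 to 2390 for CAF1 against CAF2, 5 to 48 for CD206hi against CD206pos, 747 to 1164 for CD206hi against CD206neg, 1109 to 2070 for CD206pos against CD206neg, 5533 to 6250 for endothelial cells against CAFs and 9310 to 9562 for macrophages against the rest. The lists called ran from 9 to 15, 7 to 11, 6 to 10, 6 to 9, 5 to 7 and 6 to 7 in the same order.

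Pairing by tumour as a block gave 97, 1791 and 2800 genes in the macrophage comparisons, where it removes the differences between tumours from the spread, and it gained 4 list calls: immediate early genes for CD206hi against CD206pos (0.0428, from 0.11), haem and iron handling and the cell cycle for CD206hi against CD206neg (0.0269, from 0.075, and 0.021, from 0.05) and complement for CD206pos against CD206neg (0.0225, from 0.059). Beyond these, and those given beside the results, it changed no other call of a result reported here. For CD206hi against CD206pos, DESeq2 gave 85 genes and all 30 libraries in one fit 36. A limit of 2-fold left 1079, 3949 and 5760 genes for CD206pos against CD206neg, endothelial cells against CAFs and macrophages against the rest, by its construction. Leaving out tumour 6, 10 or 11 gave 0 genes for CD206hi against CD206pos in edgeR, with 723, 437 and 609 at an unadjusted p under 0.05 and 50, 34 and 53 in DESeq2. Without tumour 5 or 8 that comparison had 30 or 19 genes in edgeR. Tumour 6 or 11 left out gave 652 or 535 for CD206hi against CD206neg, and tumours 5, 6, 10 or 11 gave 1074, 1064, 765 or 818 for CD206pos against CD206neg. Without the CD206neg libraries of tumours 6 and 8 the last 2 comparisons had 545 and 930 genes. An estimated correlation called 4 lists for CAF1 against CAF2, 3, 1 and 1 in the macrophage comparisons and 2 for macrophages against the rest. The fry test called 4 lists for CD206hi against CD206pos, 2 for CD206hi against CD206neg, 12 for endothelial cells against CAFs and 15 for macrophages against the rest, and tumour 6 left out gave 5 lists for CD206hi against CD206pos. For the tumours left out, the CD206neg libraries left out, DESeq2, the joint fit, the estimated correlation, fry and the lists without tumour 6, the cause was not tested. In CAF1 against CAF2, list calls were lost without a tumour for macrophage genes (tumour 10, 0.0661), hypoxia (tumour 6, 0.0558, and tumour 8, 0.0921) and interferon genes (tumour 5, 0.0553, and tumour 10, 0.0524). In CD206hi against CD206pos the dendritic cell and cytokine lists were lost without tumour 6 (0.0584 each). At this depth 3 counts correspond to 0.251 to 0.477 CPM, and calls were limited further by the low-count filter and by genes absent from the matrix.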

Other observations

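The groupings of libraries in this part were tested after the results were seen, and the genes follow the fixed naming rule. Of 5 lymphatic endothelial genes 3 rose and 1 fell in endothelial cells against CAFs (camera adjusted p = 0.205), with the hyaluronan receptor Lyve1 higher (log2 4.76 ± 0.71, SE, n = 5 against 10 libraries) and Pdpn lower (-5.71 ± 0.66), at edgeR adjusted p values of 2.56e-06 and 2.83e-08. Fabp4, a fatty acid carrier of capillary endothelium and of adipocytes, had a log2 fold change of 4.59 ± 0.37 (edgeR adjusted p = 2.04e-11).

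Each comparison was set beside other groupings of its libraries, 100 in all with the real one, to count how often a random division gives as many calls.

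For CAF1 against CAF2, only 1 grouping, the real one, reached 2370 genes, and the highest of the others had 0. Chance is not excluded for the 11 lists, as 29 groupings called as many, with up to 15. For CD206hi against CD206neg, only the real grouping reached 1110 genes (1 of 100, highest other 60). Chance is not excluded for its 7 lists (50 of 100, highest other 15). For CD206pos against CD206neg, only the real grouping reached 1625 genes (1 of 100, highest other 280). Chance is not excluded for its 7 lists (32 of 100, highest other 16). In these comparisons most other groupings break the pairing by tumour, and each mixes the populations compared within both sides. Their share alone therefore does not exclude chance for the gene counts. Only the real grouping reached the 6145 genes of endothelial cells against CAFs (1 of 100, highest other 1744), the 9429 genes of macrophages against the rest (1 of 100, highest other 1285) and the 23 angiogenic genes with a separated leading group (1 of 100, highest other 0). The 6 lists of endothelial cells against CAFs were reached by 51 of 100 (highest other 10) and the 6 of macrophages against the rest by 55 of 100 (highest other 13). The other groupings of these results mix lineages within each side, so they test neither the gene counts nor the list counts against chance. For macrophages against the rest, none of the other groupings keeps every tumour complete in both groups.

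For CD206hi against CD206pos chance is not excluded for 21 genes (7 of 100) or 8 lists (19 of 100, highest other 13). The highest other grouping called 789 genes, many times the real count, and parts tumours 5 and 11 from tumours 6 and 10, which points to a structure of the samples by tumour. The 13 groupings that keep every tumour in both groups called 0 genes at most in edgeR's test.

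With every tumour kept in both groups, the highest of the other groupings called 0 genes for CAF1 against CAF2 (9 groupings), CD206hi against CD206neg (13) and CD206pos against CD206neg (10). So few groupings cannot give a share under 0.05.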
